A study of Homo sapiens with 18 samples.

How the data were processed

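The samples were Flp-In-293 cells grown in DMEM with fetal bovine serum to 60 to 70% confluence, given 4sU or not, dissociated, fixed in methanol, alkylated overnight with 10 mM iodoacetamide and strained, per the labels' protocols. The labels put iodoacetamide on every sample, those with no 4sU included. Of the 18 libraries, 10 were single-cell libraries made on a Nadia instrument and 8 were bulk libraries, 2 replicates per duration of 4sU. The deposited single-cell tables hold whole-number counts per cell and gene in 4 columns (labelled or unlabelled, spliced or unspliced), per the file headers, and the deposited bulk tables hold raw counts per gene. The submitters' processing notes name STAR 2.6.0a, Picard and GRCh38 for single cells and STAR 2.6.0a, SAMtools 1.9 and GRCh38 for bulk. The counter, the annotation, whether molecules were collapsed and the rule for calling a count labelled are not given in the sources used here. Values are therefore called counts throughout.

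Gene symbols (23880 in all, 23114 of them in single cells and 20446 in bulk) were all found in GENCODE 29, from which coordinates (GRCh38), lengths and base composition were taken. Of 8228 barcodes, the 8166 with at least 1000 counts, at least 500 genes and under 20% mitochondrially encoded counts were kept. Doublets (148 called, 1.81% of kept cells) were counted and not removed. Counts of kept cells were summed per library, since cells are not replicates. Phases were scored over all libraries together from 43 S-phase and 54 G2/M genes against 100 control genes per scoring gene from 24 expression bins. The bins, the control genes and the cut at 0 were the same for every library. A cell was S or G2/M by the higher score if above 0 and otherwise G1. Counts were summed per library and phase. For the phase shares, each cell was first thinned to 3000 counts.

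Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. All 10 single-cell libraries, or all 8 bulk libraries, entered 1 fit per assay and shared an estimate of the spread, with each duration set against no 4sU. Trends took minutes of 4sU as a linear term over 0 to 60 min in single cells and over 0 to 120 min in bulk, given per hour. The assays were compared by the interaction of assay and duration over the 12 libraries at 0, 30 and 60 min, with the controls of each assay its own. Phases were compared over 30 sums with the library as a block, and genes used for scoring were left out of the counts of calls. The alternatives were DESeq2 1.42.0 (Wald test with its own filtering), DESeq2's size factors in edgeR, no filter, other minimum counts per cell, the replicate number as a block, thinned cells, cells near a phase boundary left out, the libraries with no 4sU alone, and each library or duration left out in turn. Where that left a group with 1 library, it was assumed to vary like the other groups.

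Gene lists were tested with camera (limma 3.58.1) on voom values with an inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison. The 25 lists, written from knowledge of 4sU labelling, stress and the cell cycle, were p53 targets, ribosomal proteins, ribosome biogenesis, immediate early genes, integrated stress and unfolded protein response, heat shock response, cholesterol synthesis, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, replication-dependent histones, snoRNA host and other long noncoding RNAs, NRF2 oxidative stress response, interferon response, pyrimidine nucleotide metabolism, RNA turnover and processing machinery, S-phase and G2 and mitosis genes held out of the scores, G1 genes, tubulin and microtubule, glycolysis, proteasome, zinc finger and other short-lived regulators, and markers of fibroblasts, carcinoma epithelium and blood. The tests, comparisons, lists and most alternatives were set before the data were examined. Chosen after the data were seen were the comparisons of labelled counts and labelled share between phases with all their alternatives, spliced counts alone, cells of at least 10000 counts, the 6 libraries of the shared pair of runs alone, the random scoring lists, and leaving out single libraries in the phase and assay comparisons.

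The labelled share was the percent of labelled among spliced or among unspliced counts, per library and, for genes with at least 100 spliced counts in each labelled library, per gene. Shares per library were compared between durations by an exact permutation test over all groupings of the 10 libraries into 5 pairs, and between phases by an exact sign-flip permutation test over libraries. The labelled counts of each gene, spliced and unspliced together, were compared between phases as all counts were. Its labelled share, of the same counts, was compared by the interaction of label and phase over the 6 libraries at 15, 30 and 60 min. There, TMM scaled labelled and unlabelled counts apart, so its values are relative to the typical gene. Shares per library carried exact binomial intervals of 95%. Bulk and summed single cells were compared by Pearson r and Spearman rho over genes with a mean of at least 1 CPM in both, on log2 CPM with a pseudocount of 0.5.

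The genes named per duration or trend were the 12 largest rises and 12 largest falls with an average log2 CPM of at least 3 and both labelled libraries on the same side of both controls. Per phase comparison they were the 15 largest each way with an average of at least 5 and the same sign in at least 9 of 10 libraries (6 of 6 for labelled counts and share). From each list up to 4 members with the smallest p were added. Precision was checked on simulated changes. For edgeR these were placed in counts drawn from its own fits, gene by gene, and not in the libraries' own counts. The rates below thus hold where the spread is as edgeR fits it. They do not show how often edgeR errs where genes are correlated or a pair of replicates differs more than the others. EdgeR called 51.0% of 1.5-fold and 73.0% of 2-fold changes at 60 min in single cells (14628 genes, 6.06% of calls false), 66.0% and 85.0% at 60 min in bulk (10.1% false). It called 85.0% and 99.0% between G2/M and G1 (3.66% false), 61.0% and 89.0% for labelled counts (3.85% false), and 18.0% and 63.0% for the labelled share (none false). Camera called the shifted list in 20 of 20 simulated runs and 0 of 480 other lists. Those runs drew independent normal values and not counts of these libraries. They thus do not show how often camera errs where genes are correlated. The Python tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5 for doublet calls with Scrublet, statsmodels 0.14.6 and matplotlib 3.10.9. Depth per library is given in the report.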

Results

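Flp-In-293 cells, a derivative of the human embryonic kidney line HEK293 with an integrated recombination site for transgenes, were grown with 4-thiouridine (4sU) for different times before harvest. Cells build this uridine analog into new RNA, and iodoacetamide (IAA) then alkylates it, so that it is read as cytosine and new transcripts can be told from old ones. Polyadenylated RNA was measured in 10 single-cell libraries, 2 each with no 4sU and after 15, 30 and 60 min and 24 h, and in 8 bulk libraries, 2 each with no 4sU and after 30, 60 and 120 min. The values were deposited counts per gene, and in single cells each count was also labelled or unlabelled and spliced or unspliced. The labels number the replicates without saying that they were separate cultures. The p-values therefore measured only the spread between these libraries, which may be technical. Intervals on shares covered counting error only.

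After filtering, 575 and 675 cells were kept with no 4sU, 704 and 965 at 15 min, 658 and 947 at 30 min, 1364 and 1330 at 60 min and 486 and 462 at 24 h. The median count per cell was 7487 and 6002 with no 4sU, 23541 and 16944 at 15 min, 8931 and 7591 at 30 min, 6461.5 and 7607 at 60 min and 23576 and 16382 at 24 h. Total counts per single-cell library ran from 4636656 to 18479172. By the run numbers in the deposited names, the libraries with no 4sU, 30 and 60 min shared a pair of runs, while those at 15 min and at 24 h each came from another pair. Bulk totals were 29701635 and 30687516 with no 4sU, 28037372 and 35450821 at 30 min, 31750598 and 31338759 at 60 min and 34246930 and 34050934 at 120 min. Replicates correlated across genes with r from 0.991 to 0.999 (genes are not independent replicates), except at 30 min in bulk, where r was 0.981. At 30 min in bulk, MT-ND6, a mitochondrially encoded complex I subunit, was at 283 CPM (counts scaled to the library total) in replicate 1 and 104 in replicate 2. In the bulk libraries of the other durations it ran from 255 to 322 CPM, so for this gene replicate 2 stood apart. HYPK was at 65.6 in replicate 1 and 177 in replicate 2 at 30 min. Both genes were picked after their values were seen.

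Whether labelled RNA built up with time was read from the labelled share of counts in each single-cell library. Among spliced counts, 0.00555% ± 0.000158 (SD, n = 2) were labelled with no 4sU, 3.52% ± 0.489 at 15 min, 9.93% ± 0.205 at 30 min, 15.5% ± 1.85 at 60 min and 68.1% ± 0.130 at 24 h. Unspliced counts, the precursors of mature transcripts, were labelled faster, at 0.00873% ± 0.000157, 17.5% ± 1.98, 39.1% ± 0.0912, 51.1% ± 4.29 and 87.9% ± 0.678. Both differed between durations by more than the spread between replicates (exact permutation p = 0.00106 for each over all groupings of the 10 libraries into 5 pairs, the smallest possible). The unspliced share of all counts was 1.30% ± 0.0658 with no 4sU, 1.35% ± 0.0364 at 15 min, 1.80% ± 0.0466 at 30 min, 1.55% ± 0.104 at 60 min and 0.294% ± 0.00957 at 24 h (exact permutation p = 0.00212). For all these shares, the durations of 15 min and 24 h cannot be told apart from their runs. With no 4sU, 531 spliced counts over both libraries were called labelled, 54 of them from AMBRA1.

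**Figure D1:**
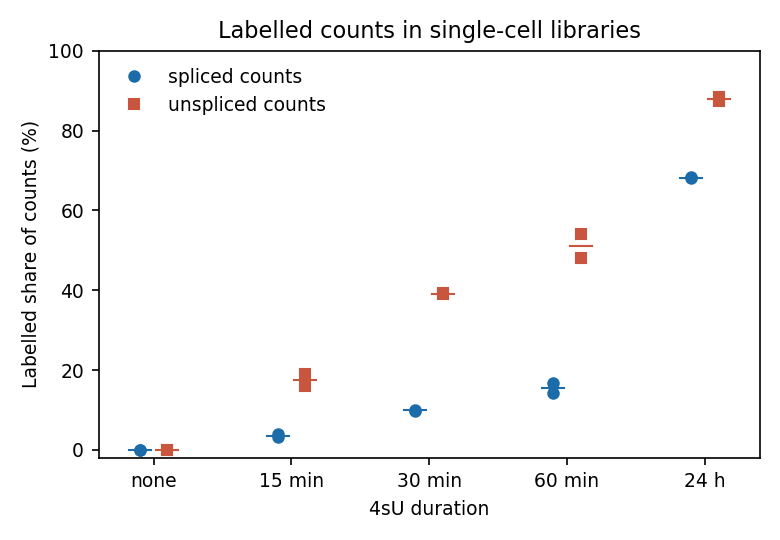
Percent of spliced and of unspliced counts that were labelled (y axis) in each single-cell library (points, 2 per duration of 4sU on the x axis), with lines at the means. The unspliced share lay above the spliced share at every duration with 4sU and reached 51.1% at 60 min against 15.5%.

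The share of a gene's spliced counts that was labelled after a short pulse follows how fast a transcript is replaced, along with changes in its level. It also depends on how many labelled reads of a gene are recognised, which was not measured. The share was taken for 8090 genes with at least 100 spliced counts in each labelled library, a minimum chosen after the data were seen. The median gene was 5.54% labelled at 15 min, 15.3% at 30 min, 24.6% at 60 min and 81.4% at 24 h. Percentiles 5 and 95 at 60 min were 5.70% and 57.8%. Among the 12 genes labelled most at 60 min were ADM, a peptide hormone precursor, at 92.7% ± 1.52 (SD, n = 2) and RGS16, which switches off G protein signalling, at 92.5% ± 0.767. So was NFKBIA, the inhibitor of NF-kappa-B, at 91.2% ± 0.0209. By 24 h these stood lower, ADM at 75.5% ± 1.30, RGS16 at 76.6% ± 0.936 and NFKBIA at 84.2% ± 3.82. The 24 h libraries came from another pair of runs, so this drop may reflect the run. At 60 min the Notch target HES1 stood at 89.6% ± 1.79 and the transcription factor MYC (GRCh38 chromosome 8, 127735434 to 127741434, plus strand) at 89.5% ± 2.32, up from 20.9% ± 1.56 at 15 min. The 12 labelled least held the noncoding RNA LINC00486, the lowest of all at 0.0382% ± 0.0467 and still only 0.497% ± 0.304 at 24 h, the dynactin subunit DCTN3 at 1.40% ± 0.136, NDUFS7 of respiratory complex I at 2.28% ± 0.0857 and COX6C of cytochrome c oxidase at 2.46% ± 0.0551. Of these, DCTN3 reached 46.9% ± 2.36 and COX6C 41.7% ± 1.45 at 24 h. LINC00486 stayed far below them, so its share was not shown to reflect slow replacement. Gene shares at 30 and 60 min had a Spearman rho of 0.961 across genes, against 0.975 between the 60 min replicates and 0.960 between the 30 min replicates.

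Gene lists fixed before the data were examined differed widely in labelled share at 60 min. Each value is the median member with, in parentheses, how many measured members lay above the median of all genes. The highest shares were 64.4% for immediate early genes (13 of 13), 61.0% for zinc finger and other short-lived regulators (14 of 17), 32.7% for G1 and early G1 genes (11 of 16) and 31.4% for p53 targets (12 of 18). Among immediate early genes, which respond within minutes to growth factors, MYC was the highest and SRF the lowest, at 31.6%. Near the median of all genes stood 28.2% for snoRNA host and other long noncoding RNAs (5 of 9), 26% for RNA turnover and processing machinery (21 of 38), 25.2% for S-phase genes not used for scoring (25 of 48), 23.5% for integrated stress and unfolded protein response (11 of 22), 21.7% for G2 and mitosis genes not used for scoring (19 of 50), 20.8% for pyrimidine nucleotide metabolism (7 of 18) and 20.4% for mitochondrially encoded (6 of 13). Lower shares were found at 19.9% for cholesterol synthesis (6 of 22), 19.7% for interferon response (2 of 5), 18.8% for ribosome biogenesis (13 of 38), 13.7% for replication-dependent histones (0 of 5), 13% for heat shock response (2 of 17) and 11% for tubulin and microtubule (1 of 11). The lowest shares were 9.17% for glycolysis (4 of 17), 9.10% for proteasome (0 of 31), 8.76% for NRF2 oxidative stress response (2 of 15), 4.91% for nuclear-encoded oxidative phosphorylation (0 of 45) and 4.24% for ribosomal proteins (0 of 76). No ribosomal protein transcript exceeded 6.80%. These are values with no test between lists.

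Cells were assigned to G1, S or G2/M by the higher of 2 scores, from 43 S-phase and 54 G2/M genes, so a phase is a range of a score and not a cell type. Of the kept cells, 4177 of 8166 (51.2%) lay within 0.1 of a boundary. With cells thinned to 3000 counts, G2/M took 32.3% ± 1.81 (SD, n = 2) of cells with no 4sU, 25.3% ± 0.882 at 15 min, 28.8% ± 1.88 at 30 min, 30.3% ± 3.46 at 60 min and 45.9% ± 3.48 at 24 h. G1 took 41.9% ± 1.98, 43.1% ± 0.410, 45.4% ± 0.282, 42.5% ± 3.74 and 25.6% ± 4.92 in the same order. S took 25.8% ± 3.79, 31.7% ± 0.471, 25.8% ± 1.60, 27.2% ± 0.276 and 28.6% ± 1.44. Only the G2/M share differed between durations after adjustment over the 3 phases (exact permutation p = 0.0138, adjusted p = 0.0413, G1 adjusted p = 0.0683, S adjusted p = 0.123). Without thinning, G2/M stood at 32.1% ± 0.210 with no 4sU and 47.7% ± 3.80 at 24 h (exact permutation adjusted p = 0.0254). Thinning left out 912 shallower cells. Free RNA, which phase calls also read, was not measured and stays open. Durations of 15 min and 24 h cannot be told apart from their runs.

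**Figure D2:**
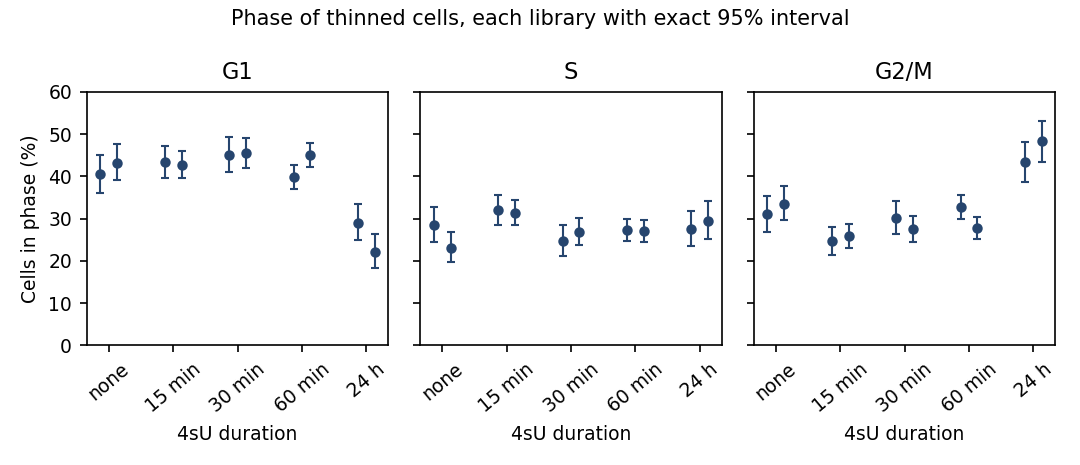
Percent of thinned cells in G1, S and G2/M (y axis) in each single-cell library, by duration of 4sU (x axis), with exact 95% binomial intervals that cover counting error only. The G2/M share was 45.9% on average at 24 h against 32.3% with no 4sU.

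S and G1 were compared within each of the 10 libraries to ask which transcripts follow the cell cycle. The median count per cell was higher in S than in G1 in 10 of 10 libraries (14293.6 against 10061 on average, exact sign-flip permutation p = 0.00195). It was also higher in G2/M than in G1 in 10 of 10 (12981.4 on average, the same p). The differences from G1 below thus also compare cells of unlike depth. FAM111B, a protease gene expressed in S phase (GRCh38 chromosome 11, 59107185 to 59127410, plus strand), was higher by 1.62 ± 0.06 log2 or 3.08-fold (157 ± 16.2 against 49.6 ± 7.73 CPM, mean ± SD, n = 10, adjusted p = 1.0e-33). A value in parentheses after other genes is the log2 change. Cyclin E1 (CCNE1), which drives entry into S, stood at 1.20 ± 0.08 (adjusted p = 2.3e-21). Also higher were E2F2 (1.81), E2F7 (0.98), TCF19 (0.89) and FBXO5 (0.85), the last encoding an inhibitor of the anaphase-promoting complex. The histone chaperone gene ASF1B (0.82), the CDK1-inhibiting kinase gene PKMYT1 (0.77), the BRCA1 partner BARD1 (0.73), thymidine kinase TK1 (0.70) and the replication factor MCM10 (0.67) were higher too. Lower in S were PLK1, a mitotic kinase (-1.07, 29.4 ± 4.29 against 57.7 ± 8.02 CPM), cyclin B1 (CCNB1, -1.05) and the kinesin gene KIF20A (-1.04). With them were lower securin (PTTG1, -0.55), DEPDC1 (-0.53), MYC (-0.31), SOX4 (-0.30) and CDKN1B (-0.28).

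Of 48 S-phase genes held out of the scores, 43 were higher in S than in G1 and none lower (45 higher adjusted over the list alone, adjusted p = 2.8e-42, and adjusted p = 3.6e-08 with an estimated correlation). Ribosomal proteins fell in 76 of 76, among them RPS29 (-0.30) and RPS14 (-0.27) (76 adjusted over the list alone, adjusted p = 6.9e-57, adjusted p = 0.190 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes such as UQCRQ (-0.27) and COX5B (-0.26) fell in 36 of 45 (39 adjusted over the list alone, adjusted p = 1.1e-18, adjusted p = 0.346 with an estimated correlation). Proteasome genes such as PSMC6 (-0.30) and PSMB1 (-0.20) fell in 24 of 31 (27 adjusted over the list alone, adjusted p = 8.7e-10, adjusted p = 0.468 with an estimated correlation). Ribosome biogenesis genes fell in 13 of 38 (13 adjusted over the list alone), LYAR (-0.29) and NHP2 (-0.22) among them (adjusted p = 2.5e-04, adjusted p = 0.468 with an estimated correlation). Held-out G2 and mitosis genes were split, with 10 higher, 18 lower and 22 not passing (median -0.03, adjusted p = 0.0680). By edgeR's quasi-likelihood test, 1416 of 11736 genes were higher and 1677 lower. The count was 908 with thinned cells, 817 of them called the same way as before. It was 462 in the 2 libraries with no 4sU alone.

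Between G2/M and G1, mitotic genes were among the largest rises. PLK1 (GRCh38 chromosome 16, 23677656 to 23690367, plus strand) rose by 1.59 ± 0.06 log2 or 3.01-fold (177 ± 49.3 against 57.7 ± 8.02 CPM, mean ± SD, n = 10, adjusted p = 2.0e-32). Cyclin B1 (CCNB1) rose by 1.30 ± 0.05 (333 ± 37.9 against 135 ± 13.5 CPM). The kinesin genes KIF20A (1.49), KIFC1 (1.36) and KIF14 (1.32), the spindle gene ASPM (1.21) and the importin gene KPNA2 (1.15) were higher. Shugoshin SGO2 (1.15), the midzone genes PRC1 (1.04) and RACGAP1 (1.02) and the checkpoint kinase gene BUB1B (1.00) were higher too, with DEPDC1 (1.45), CCNF (1.22) and ARHGAP11A (1.09). The rises also held the cell cycle inhibitor CDKN1B (0.54), the transcription factor KLF6 (0.86) and the nuclear noncoding RNA MALAT1 (0.51). Lower in G2/M were E2F1 (-1.61), the E2F factor that turns on S-phase genes, and the mismatch repair gene MSH6 (-0.77). The recombination genes MMS22L (-0.65) and XRCC2 (-0.60) and the replicative helicase gene MCM3 (-0.50) were lower as well, with FBXL20 (-1.26), FAM111B (-1.14), CCNE1 (-1.11), SNHG19 (-0.75) and ID3 (-0.60). DBF4, an activator of replication origins, was higher (0.71).

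Held-out G2 and mitosis genes were higher in G2/M than in G1 for 47 of 50 (48 adjusted over the list alone, adjusted p = 1.5e-89, and adjusted p = 3.8e-04 with an estimated correlation). Held-out S-phase genes were lower for 31 of 48 and higher for 2 (33 lower adjusted over the list alone, adjusted p = 2.2e-16, and adjusted p = 4.6e-05 with an estimated correlation). Tubulin and microtubule genes rose in 8 of 11 (10 adjusted over the list alone), led by TUBA1C (0.75) and TUBB (0.36) (adjusted p = 1.1e-06, adjusted p = 0.125 with an estimated correlation). Heat shock genes rose in 10 of 19 and fell in 1 (12 higher adjusted over the list alone, adjusted p = 1.9e-05, adjusted p = 0.125 with an estimated correlation), with UBB (0.29), STIP1 (0.26) and HSP90AA1 (0.18). Stress response genes rose in 11 of 30 and fell in 1 (12 higher adjusted over the list alone, adjusted p = 0.00112, adjusted p = 0.602 with an estimated correlation), with SLC7A11 (0.74), HSP90B1 (0.26) and ATF4 (0.21). Ribosome biogenesis genes such as DDX10 (0.46) and NCL (0.25) rose in 15 of 38 and fell in 1 (18 higher adjusted over the list alone, adjusted p = 3.9e-05, adjusted p = 0.572 with an estimated correlation). By edgeR, 1265 of 11736 genes were higher and 1183 lower. Thinned cells gave 580 calls, 480 of them the same way, and the libraries with no 4sU alone gave 249.

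Set against S, G2/M differed most. PLK1 stood at 2.66 ± 0.07 (177 ± 49.3 against 29.4 ± 4.29 CPM, adjusted p = 6.6e-44), KIF20A at 2.53 ± 0.07, CCNB1 at 2.34 ± 0.06 and DEPDC1 at 1.98 ± 0.05. In turn, FAM111B stood at -2.76 ± 0.06 (22.2 ± 4.88 against 157 ± 16.2 CPM, adjusted p = 3.5e-46), CCNE1 at -2.31 ± 0.08, MCM10 at -1.19 ± 0.05 and the DNA ligase gene LIG1 at -1.06 ± 0.05. Also higher were TUBA1C (1.08), KNSTRN (1.17), CCNG2 (1.02), CDKN1B (0.82), TOB1 (0.57), ATF4 (0.49) and PSMD7 (0.46). Also lower were E2F2 (-2.71), TCF19 (-1.38), MSH6 (-1.26), ID3 (-0.82) and IRF1 (-1.02). Held-out G2 and mitosis genes were higher for 45 of 50 (45 adjusted over the list alone, adjusted p = 0.0199 with an estimated correlation). Held-out S-phase genes were lower for 45 of 48 (45 adjusted over the list alone, adjusted p = 1.2e-07 with an estimated correlation). Ribosomal proteins were higher for 74 of 76 (74 adjusted over the list alone, adjusted p = 0.413 with an estimated correlation). Pyrimidine nucleotide genes such as DCTPP1 (-0.47) and UCK1 (-0.44) were lower for 10 of 22 and higher for 3 (11 lower adjusted over the list alone, adjusted p = 0.0217, adjusted p = 0.40 with an estimated correlation). By edgeR, 3023 of 11736 genes were higher and 2577 lower. The count was 1899 with thinned cells, 1804 of them the same way, and 938 with the libraries with no 4sU alone. Scores from 5 pairs of random lists matched on expression, an alternative chosen after the data were seen, gave 12 to 4374 calls for S against G1, 3 to 2513 for G2/M against G1 and 33 to 1947 for G2/M against S. For S against G1 and for G2/M against G1, a count of calls alone thus does not set the phases apart from ranges of another score. For G2/M against S no draw reached the real count.

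The labelled part of the counts showed which of these differences were present in new RNA. These comparisons, over the 6 libraries with 15 to 60 min of 4sU, were chosen after the data were seen. Of spliced counts, 11% were labelled in S, 9.54% in G1 and 8.5% in G2/M on average. The log2 ratio of these shares was 0.20 ± 0.04 (SD, n = 6) for S over G1, above 0 in 6 of 6 libraries, and -0.21 ± 0.12 for G2/M over G1, above 0 in none of 6 (exact sign-flip permutation p = 0.0312 for each, the smallest possible). Unspliced counts made up 1.40% in S, 1.24% in G1 and 1.15% in G2/M over all 10 libraries. Their share was higher in S than in G1 in 9 of 10 (exact permutation p = 0.00977) and lower in G2/M than in G1 in 10 of 10 (exact permutation p = 0.00195, the smallest possible). In labelled counts, E2F2 was 1.91 ± 0.22 and FAM111B 1.42 ± 0.14 higher in S than in G1, ASF1B 0.91 ± 0.11, and the kinesin gene KIFC1 1.15 ± 0.22. Lower were MYC (-0.51), SOX4 (-0.42), JUN (-0.34) and SNHG19 (-0.66). In G2/M against G1, KIF20A (1.93), DEPDC1 (1.66), CCNB1 (1.51), KIF14 (1.33), PTTG1 (1.23) and KLF6 (0.90) were higher and FAM111B (-1.39), CCNE1 (-1.19), MCM3 (-1.14), PCLAF (-1.13) and ZNF367 (-1.08) lower. In G2/M against S, E2F1 stood at -3.35 ± 0.40 (4.60 ± 2.64 against 45.6 ± 15.5 CPM of labelled counts).

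Among labelled counts in S against G1, held-out S-phase genes were higher for 21 of 47 (25 adjusted over the list alone, adjusted p = 1.0e-04 with an estimated correlation). Ribosomal proteins were lower for 59 of 75 (69 adjusted over the list alone, adjusted p = 2.1e-04 with an estimated correlation) and mitochondrially encoded genes lower for 9 of 13 (11 adjusted over the list alone, adjusted p = 7.2e-05 with an estimated correlation). Held-out G2 and mitosis genes leaned higher in S, with 5 higher and 2 lower of 48 (14 higher and 3 lower adjusted over the list alone, median 0.27, adjusted p = 0.0291 with an estimated correlation). In G2/M against G1 that list was higher for 32 of 48 (39 adjusted over the list alone, adjusted p = 2.1e-06 with an estimated correlation). There, held-out S-phase genes were lower for 20 of 47 and higher for 1 (29 lower adjusted over the list alone, adjusted p = 4.6e-05 with an estimated correlation). The mitochondrially encoded genes such as MT-ND2 (0.32) and MT-CO1 (0.23) were higher for 13 of 13 (13 adjusted over the list alone, adjusted p = 2.9e-06 with an estimated correlation). By edgeR, 237 of 7581 genes were higher and 231 lower in S against G1, 117 and 112 in G2/M against G1, and 652 and 689 in G2/M against S. Without replicate 1 or 2 at 60 min the count for S against G1 was 263 or 229. Without replicate 2 at 60 min the others were 146 and 871.

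**Figure D3:**
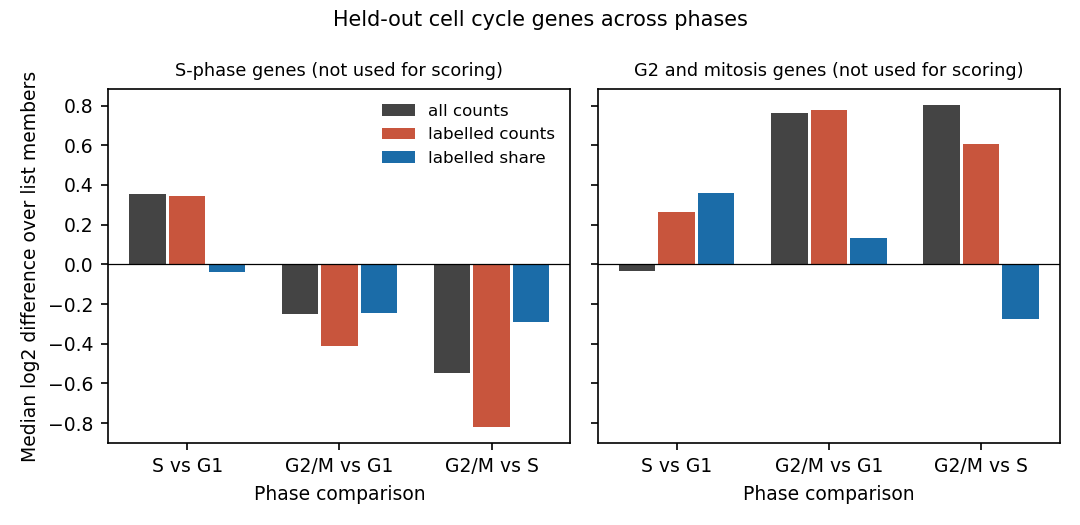
Median log2 difference (y axis, bars from 0) of held-out S-phase and held-out G2 and mitosis genes in the 3 phase contrasts, for all counts, for labelled counts and for the labelled share (labelled over unlabelled counts, relative to the typical gene). In all counts of G2/M against G1 the medians were 0.76 for G2 and mitosis genes and -0.25 for S-phase genes.

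The labelled share of each gene between phases was tested as the interaction of label and phase. Labelled and unlabelled counts were each scaled to their own totals, which removes the overall shifts in labelled share given above. The log2 odds are thus relative to the typical gene and do not show by themselves whether a gene's own share rose or fell, while the percents are its own share. In S against G1 the relative share was higher for some genes of chromosome segregation. The chromokinesin KIF4A went from a mean of 15.3% labelled in G1 to 28.9% in S (1.04 ± 0.16 log2 odds, adjusted p = 6.5e-07). Higher too were the kinetochore gene SPC25 (0.92), DEPDC1B (0.85), the condensin gene NCAPG (0.60) and the tubulin genes TUBA1C (0.48) and TUBB (0.30). The histone gene HIST1H4C (GRCh38 chromosome 6, 26103876 to 26104310, plus strand) went from 7.10% to 12.6% (0.75 ± 0.05, adjusted p = 3.2e-40) and was back at 4.82% in G2/M (-1.09 ± 0.05 against S). Its near-identical copies and polyadenylated-only capture leave it uncertain. Lower in S were the immediate early genes ATF3 (-1.20) and JUN (-0.52), MCM3 (-0.50), MALAT1 (-0.28) and MT-ND4 (-0.29). Between G2/M and G1 the relative share was higher for securin PTTG1 (0.96), TROAP (0.85), PIGM (1.05), SNHG19 (0.76), RPL23 (0.45) and MT-CO1 (0.34) and lower for PCLAF (-0.99), DUT (-0.86), MCM3 (-0.66), H2AFY2 (-0.98), TCF7L2 (-0.88) and MALAT1 (-0.46). PCLAF, a partner of the replication clamp, went from 4.98% to 2.16%. G2/M against S gave relative values of SNHG19 (1.21), MT-CO3 (0.59), FDPS (-0.59), TUBB (-0.66) and FANCI (-0.71).

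By list, the relative labelled share in S against G1 was higher for 4 of 50 held-out G2 and mitosis genes (21 adjusted over the list alone, median 0.36, adjusted p = 2.0e-04 with an estimated correlation). It was lower for 7 of 13 mitochondrially encoded genes (12 adjusted over the list alone, median -0.24, adjusted p = 0.00154 with an estimated correlation). Histones gave 1 of 10 higher (2 adjusted over the list alone, median 0.36, adjusted p = 0.00159 with an estimated correlation) and tubulin genes 2 of 11 (3 adjusted over the list alone, adjusted p = 0.00511 with an estimated correlation). In G2/M against G1, ribosomal proteins were relatively higher for 25 of 76 (55 adjusted over the list alone, median 0.19, adjusted p = 9.2e-05 with an estimated correlation). So were mitochondrially encoded genes for 12 of 13 (13 adjusted over the list alone, adjusted p = 9.2e-05 with an estimated correlation) and oxidative phosphorylation genes for 3 of 45 (3 adjusted over the list alone, median 0.14, adjusted p = 0.0143 with an estimated correlation), and held-out S-phase genes were lower for 6 of 48 (14 adjusted over the list alone, adjusted p = 0.00869 with an estimated correlation). In G2/M against S, held-out G2 and mitosis genes were lower for 8 and higher for 2 of 50 (16 lower adjusted over the list alone, median -0.28, adjusted p = 0.00459 with an estimated correlation). Mitochondrially encoded genes were higher for 13 of 13 (13 adjusted over the list alone, adjusted p = 1.2e-05 with an estimated correlation) and ribosomal proteins for 50 of 76 (65 adjusted over the list alone, median 0.29, adjusted p = 4.2e-05 with an estimated correlation). Held-out S-phase genes were lower for 6 of 48 (14 lower and 3 higher adjusted over the list alone, adjusted p = 0.00789 with an estimated correlation). Cholesterol synthesis genes were lower for 3 of 24 (4 adjusted over the list alone, adjusted p = 0.0117 with an estimated correlation). The medians of mitochondrially encoded genes in S against G1, of ribosomal proteins in both G2/M comparisons and of oxidative phosphorylation genes in G2/M against G1 are close to or below the overall shift of the other sign in size. The share itself of these lists is thus not shown to have moved. By edgeR, the relative share was higher for 19 and lower for 25 of 11462 genes in S against G1, 82 and 84 in G2/M against G1, and 174 and 100 in G2/M against S. Without replicate 1 or 2 at 60 min these counts were 27 or 17, 61 or 57, and 170 or 125. Without replicate 2 at 30 min the G2/M against G1 count was 97. DESeq2 gave 12, 46 and 125.

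Whether 4sU itself changed transcript levels was asked by comparing each duration with no 4sU. A lower count may also reflect a loss of labelled RNA or of its reads, which is taken up at the end. In single cells at 60 min, CYR61, a secreted matrix protein and immediate early gene, fell by 1.76 ± 0.24 log2 (2.58 ± 0.207 against 8.96 ± 0.775 CPM, mean ± SD, n = 2, adjusted p = 1.4e-04). MYC fell by 0.76 ± 0.14 (43.7 ± 1.80 against 75.2 ± 9.93 CPM, adjusted p = 0.00464). The mTOR inhibitor DDIT4 (-0.95), ADM (-0.86) and the protease ADAMTS1 (-0.76) fell, and so did the transcription factor SOX4 (-0.52), the heat shock gene HSPA1B (-0.65) and PPP1R10 (-0.58), ETAA1 (-0.52), ZNF230 (-0.69) and ZNF420 (-0.46). Rises included the mitochondrial complex I gene MT-ND4L (0.68), the polyamine regulator OAZ1 (0.60), LINC00886 (1.03), AL136454.1 (0.71), EID2B (0.73) and OOEP (0.58). The rises of H3F3A (1.06), RPL17 (0.84) and HNRNPA1P48 (0.84) are uncertain, since these genes may share reads with near-identical copies. The noncoding RNA AC009478.1 was at 19.7 ± 1.62 against 0.414 ± 0.0249 CPM, the second from few counts. At 30 min, BTG2 (-0.73) and ADAMTS1 (-0.39) fell, BTG2 being an antiproliferative immediate early gene. At the same time AC004448.2 (1.31), H3F3A (1.22), RPL17 (1.03), LINC00486 (1.08), LSAMP (1.07) and MT-ND4L (0.67) rose. The spliced counts of LINC00486 were almost all unlabelled (0.0204% ± 0.0102 labelled at 30 min), so new RNA is not shown to account for its rise.

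Immediate early genes fell in 2 of 28 at 60 min (13 adjusted over the list alone, median -0.46, adjusted p = 1.1e-12, adjusted p = 0.322 with an estimated correlation). At 30 min they fell in 1 of 28 (1 adjusted over the list alone, median -0.30, adjusted p = 4.8e-04, adjusted p = 0.554 with an estimated correlation). Zinc finger and other short-lived regulators gave 1 of 27 lower at 60 min (7 adjusted over the list alone, median -0.23, adjusted p = 7.0e-07, adjusted p = 0.322 with an estimated correlation). No list call at 30 or 60 min held with an estimated correlation. At 30 min the median of ribosomal proteins was -0.09 (adjusted p = 5.6e-04, adjusted p = 0.786 with an estimated correlation), yet 2 of 76 rose and 0 fell (2 and 0 adjusted over the list alone). By edgeR, 50 of 14628 genes were higher and 5 lower at 30 min, and 35 and 14 at 60 min. DESeq2 called 38 and 2 at 30 min and 23 and 8 at 60 min. The 30 min count was 13 or 31 without replicate 1 or 2 at 30 min, 14 or 16 without a no 4sU replicate and 83 without either 24 h replicate. The 60 min count was 18 without replicate 2 at 60 min, 10 without replicate 1 with no 4sU and 80 or 81 without a 24 h replicate. With the 6 libraries of their shared runs alone, the counts were 97 and 84. They held all 55 and 49 genes called with all libraries, each with the same direction as before. With cells of at least 10000 counts they were 19 and 16.

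At 15 min, where the duration cannot be told apart from the pair of runs, mitochondrially encoded genes rose in 9 of 13 (13 adjusted over the list alone, median 0.41, adjusted p = 9.3e-20, adjusted p = 0.233 with an estimated correlation). The largest of these was MT-ND4L at 1.02 ± 0.09 (507 ± 10.1 against 266 ± 21.6 CPM, adjusted p = 9.5e-09) with MT-ND1 (0.61), MT-CO1 (0.55) and MT-CO3 (0.49). Stress response genes fell in 5 of 32 (10 lower and 1 higher adjusted over the list alone, median -0.23, adjusted p = 2.6e-05, adjusted p = 0.233 with an estimated correlation). Among them were the amino acid transporter SLC7A5 (-1.18), DDIT4 (-0.73) and the chaperone HSPA5 (-0.41). Immediate early genes fell in 3 of 28 (CYR61 (-0.84), JUN (-0.36) and SGK1 (-1.07); 6 adjusted over the list alone; adjusted p = 0.00459; adjusted p = 0.601 with an estimated correlation). HSPA1B (-1.37), thioredoxin reductase TXNRD1 (-0.73), heme oxygenase HMOX1 (-0.98), the nuclear RNA NEAT1 (-0.53) and HES4 (-1.42) fell too. Of the markers of other cell types, HBA1 (-1.12) of the blood list fell, 1 of 2 (1 adjusted over the list alone, median -0.96). So did MMP2 (-1.85) of the fibroblast list, 1 of 3 (2 adjusted over the list alone, median -0.70, adjusted p = 0.192, adjusted p = 0.601 with an estimated correlation). The largest falls were of genes nearly absent at 15 min, such as the chloride transporter SLC26A3 (0.393 ± 0.0198 against 19.2 ± 5.56 CPM) and the muscarinic receptor CHRM2 (0.343 ± 0.255 against 13.8 ± 0.629 CPM), with AK5 (-2.74), INO80D (-2.63), ASTN2 (-2.31) and SLC30A10 (-1.90). Rises included AMBRA1, a regulator of autophagy, at 1.39 ± 0.10 (375 ± 45.8 against 152 ± 13.2 CPM), DAB2IP (1.16), MAMDC2 (1.10), ZCCHC12 (1.00), RPS2 (0.62), RPSA (0.55) and RRP1 (0.59). The rises of UQCRHL (1.52) and PGAM1 (0.95) are uncertain because of near-identical copies. That of AMBRA1 is uncertain too, since it held more of the counts called labelled with no 4sU than any other gene. Ribosomal proteins rose in 7 of 76 and fell in 1 (17 and 2 adjusted over the list alone, adjusted p = 5.6e-13, adjusted p = 0.601 with an estimated correlation). By edgeR, 209 of 14628 genes were higher and 423 lower. The count was 308 with cells of at least 10000 counts, 352 or 277 without replicate 1 or 2 at 15 min and 194 or 357 without replicate 1 or 2 with no 4sU.

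At 24 h, again confounded with the runs, transcripts of the ribosome, of respiration and of sterol synthesis were lower. Ribosomal proteins fell in 68 of 76 and rose in 4 (68 lower adjusted over the list alone, median -1.06, adjusted p = 4.7e-38, adjusted p = 0.393 with an estimated correlation). Examples were RPS27 (-2.81), RPL39 (-2.77) and RPS29 (-2.45), with RPS26 (-3.61) uncertain because of near-identical copies. Mitochondrially encoded genes fell in 12 of 13 (MT-ND3 (-1.90), MT-ND2 (-1.56) and MT-CO3 (-1.23); 12 adjusted over the list alone; adjusted p = 3.0e-10; adjusted p = 0.393 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 36 of 46, with 5 higher (COX7B (-1.75), COX8A (-1.46) and NDUFA1 (-1.41); 36 lower adjusted over the list alone; adjusted p = 4.9e-12; adjusted p = 0.393 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 24 and rose in 1 (13 lower adjusted over the list alone, adjusted p = 9.9e-06, adjusted p = 0.249 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell by 1.89 ± 0.09 (49.9 ± 2.57 against 152 ± 11.6 CPM, adjusted p = 5.2e-16), with INSIG1 (-1.96), SQLE (-1.71) and IDI1 (-1.51). Heat shock genes fell in 14 of 20 (HSPB1 (-2.99), HSPA1B (-1.58) and CHORDC1 (-0.84); 14 lower and 2 higher adjusted over the list alone; adjusted p = 5.2e-04; adjusted p = 0.393 with an estimated correlation). Histones fell in 8 of 15 (8 adjusted over the list alone, adjusted p = 0.00965, adjusted p = 0.398 with an estimated correlation). Held-out S-phase genes rose in 21 of 48 and fell in 8 (21 and 9 adjusted over the list alone, adjusted p = 0.0265, adjusted p = 0.472 with an estimated correlation). Among these were MCM7 (1.29), CDT1 (1.24) and CDC25A (1.26), all higher, and PCLAF (-1.10), which was lower.

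The largest rises at 24 h included the ubiquitin-conjugating enzyme gene CDC34 at 2.23 ± 0.16 (64.6 ± 10.2 against 11.3 ± 1.36 CPM, mean ± SD, n = 2, adjusted p = 4.4e-12), UBALD2 (2.15), TRIP6 (1.99), CTDP1 (1.91), PPP1R12C (1.89) and UBXN6 (1.84) and the Polycomb gene RING1 (1.83). The largest falls included the snoRNA host genes SNHG25 (-3.66) and SNHG9 (-3.65), the calcium-binding S100A11 (-3.58, 8.85 ± 1.79 against 87.1 ± 10.1 CPM), C4orf48 (-3.82) and DGKI (-3.37) and CHRM2 (0.453 ± 0.0931 against 13.8 ± 0.629 CPM). MYC (-1.56), HES1 (-1.79), ID3 (-1.70) and SOX4 (-1.17) fell. The glycolytic genes ENO1 (0.71) and GPI (0.90) and the survival gene MCL1 (1.04) rose. Markers of other cell types moved as well. Of the blood list, HBA1 (-4.97, 0.448 ± 0.0227 against 11.9 ± 1.33 CPM) and its near-identical copy HBA2 (-3.61), the only members measured, fell. Of the carcinoma epithelium list, CDKN2A (-1.07), EPCAM (-0.54) and CDH1 (-1.60) fell, 3 of 4 (3 adjusted over the list alone, adjusted p = 0.0647). Of the fibroblast list, MMP2 (-2.73) fell, 1 of 3 (adjusted p = 0.822). The fibroblast list's median, 0.18, and its test differed in sign. By edgeR, 3661 of 14628 genes were higher and 3462 lower at 24 h.

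The trend per hour over 0 to 60 min in single cells asked for gradual change. Its 15 min libraries came from another pair of runs, so at 15 min duration and run cannot be told apart. The trend called 2 genes higher and 1 lower of 13953 by edgeR (1198 at an unadjusted p under 0.05, and 13 and 6 by DESeq2). MYC fell by 0.84 ± 0.13 per hour (adjusted p = 0.0398). The noncoding RNA AP003481.1 was at 20.2 ± 3.44 against 0.737 ± 0.482 CPM at 60 min against no 4sU. Of the immediate early genes, 1 of 28 fell (9 adjusted over the list alone, median -0.37, adjusted p = 1.1e-07, adjusted p = 0.0555 with an estimated correlation). Of zinc finger and other short-lived regulators none passed (0 adjusted over the list alone), though their median was -0.20 (adjusted p = 3.8e-05, adjusted p = 0.0470 with an estimated correlation). The count was 0 without either 60 min replicate and without replicate 1 with no 4sU, 1 without replicate 2 with no 4sU, and 8 or 9 without a 15 min replicate. With the replicate number as a block it was 0, so MYC lost its call.

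In bulk, immediate early genes were among the falls. EGR1, an immediate early transcription factor (GRCh38 chromosome 5, 138465490 to 138469315, plus strand), was at 23.4 ± 1.51 against 69.8 ± 0.472 CPM (mean ± SD, n = 2) at 30 min and with no 4sU. It fell by 1.53 ± 0.09 log2 (adjusted p = 2.0e-04) at 30 min and fell by 1.73 ± 0.09 at 60 min. With it fell at 30 min the pseudokinase TRIB1 (-1.10), the phosphatase DUSP1 (-0.98), FOS (-1.36), ADAMTS1 (-0.96), KLF6 (-0.83), SOX4 (-0.76), CYR61 (-0.69), SPRY1 (-0.84) and RGS16 (-0.63). So did the cyclin gene CCNL1 (-0.66) and the helicase gene EIF4A2 (-0.60). At 60 min TRIB1 (-1.35), KLF6 (-1.05), PPP1R10 (-1.05), CITED2 (-0.87) and MYC (-0.54) fell, with the chaperone gene DNAJB9 (-1.19) and the phosphatase DUSP6 (-1.22). The cytoskeletal crosslinker MACF1 (0.96 ± 0.16), VPS13A (0.73), UTRN (0.64) and SETD2 (0.56) and the RNA polymerase II subunit POLR2A (0.68) rose. Immediate early genes fell in 6 of 32 at 30 min (20 adjusted over the list alone, adjusted p = 1.8e-21, adjusted p = 0.122 with an estimated correlation). At 60 min they fell in 17 (24 adjusted over the list alone, adjusted p = 7.9e-28, adjusted p = 0.0752 with an estimated correlation). Short-lived regulators fell in 2 at 30 min and 14 at 60 min of 28 (13 and 19 adjusted over the list alone, adjusted p = 6.9e-18 at 60 min, adjusted p = 0.253 with an estimated correlation). Mitochondrially encoded genes rose in 3 of 13 at 60 min (11 adjusted over the list alone, adjusted p = 7.1e-08, adjusted p = 0.253 with an estimated correlation).

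By edgeR, 0 of 14285 genes were higher and 14 lower at 30 min in bulk (1642 at an unadjusted p under 0.05). DESeq2 called 24 higher and 102 lower. At 60 min 116 were higher and 369 lower by edgeR. These counts rested on single libraries. For the 30 min count this held above all for the 30 min pair, whose replicates differed most. The 60 min count rested on the replicates at 60 min and with no 4sU as well. Leaving out either 30 min replicate also took the difference of that pair out of the shared estimate of the spread. The 30 min count was 5129 (2541 higher and 2588 lower) without replicate 1 at 30 min and 528 (335 higher and 193 lower) without replicate 2, so the direction of the calls did not hold. It was 2 without either 60 min replicate, 4 or 5 without a 120 min replicate and 1 without either no 4sU replicate. The 60 min count was 3223 without either 30 min replicate (1669 higher and 1554 lower without replicate 1, 1488 higher and 1735 lower without replicate 2). It was 2 or 4 without a 60 min replicate, 228 or 235 without a 120 min replicate and 3 without either no 4sU replicate.

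After 120 min in bulk, EGR1 was at 12.9 ± 0.672 against 69.8 ± 0.472 CPM with no 4sU, -2.29 ± 0.09 log2 (adjusted p = 6.3e-06), and the amino acid transporter SLC38A2 at -2.03 ± 0.16 (55.8 ± 0.850 against 251 ± 15.7 CPM). TRIB1 stood at -2.01 ± 0.14 and PCF11, a factor of transcript 3' end formation, at -1.99 ± 0.09. Immediate early genes fell in 25 of 32 (26 adjusted over the list alone, median -0.93, adjusted p = 4.2e-14, adjusted p = 0.259 with an estimated correlation). Short-lived regulators fell in 22 of 28 (ARRDC4 (-1.61), ZBTB10 (-1.33), SOX4 (-1.13) and CITED2 (-1.09); 22 adjusted over the list alone; adjusted p = 6.5e-12; adjusted p = 0.354 with an estimated correlation). G1 genes fell in 11 of 18, with 1 higher (FOXO3 (-1.13) and MYC (-0.91); 11 lower adjusted over the list alone; adjusted p = 6.1e-04; adjusted p = 0.354 with an estimated correlation). The p53 targets fell in 12 of 28, with 2 higher (BTG2 (-1.03) and MDM2 (-0.72); 13 lower adjusted over the list alone; adjusted p = 0.00739; adjusted p = 0.444 with an estimated correlation). Ribosomal proteins rose in 44 of 76 (RPL7 (0.46) and RPL26 (0.48); 47 adjusted over the list alone; adjusted p = 6.2e-12; adjusted p = 0.354 with an estimated correlation). Mitochondrially encoded genes did so in 11 of 13 (MT-ATP6 (0.63) and MT-ND4 (0.61); 11 adjusted over the list alone; adjusted p = 3.5e-06; adjusted p = 0.354 with an estimated correlation). Oxidative phosphorylation genes rose in 18 of 46 (23 adjusted over the list alone, adjusted p = 8.3e-07, adjusted p = 0.356 with an estimated correlation) and proteasome genes in 8 of 31 (8 adjusted over the list alone, adjusted p = 6.6e-05, adjusted p = 0.474 with an estimated correlation). Single genes that rose were MACF1 (0.99), VPS13A (0.95), SLC25A27 (0.95), UTRN (0.87), DYNC2H1 (0.75) and SYNE2 (0.74) and the DNA repair kinase PRKDC (0.75, 1198 ± 52.7 against 785 ± 46.8 CPM). Others that fell were C2orf69 (-2.09), RSBN1 (-1.99), PAPOLG (-1.90) and MAP3K1 (-1.84).

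Across 8081 genes with a labelled share, the change in bulk at 120 min followed the share labelled at 60 min in single cells. The Spearman rho was -0.577 across genes, against -0.183 for the change at 60 min. The median log2 change at 120 min was 0.25 in the decile of genes labelled least and -0.53 in the decile labelled most. By edgeR, 1984 of 14285 genes were higher and 2598 lower at 120 min. Of the calls 43.3% were higher, against 30.7% of 4125 calls with DESeq2's size factors. The 120 min count was 2536 or 2020 without replicate 1 or 2 at 120 min, 2161 or 2190 without one with no 4sU and 8024 or 7566 without one at 30 min. The percent of calls higher ran from 15.0% without replicate 2 at 120 min to 55.6% without replicate 1 at 30 min. The bulk trend over 0 to 120 min called 2130 higher and 2568 lower (45.3% higher, or 33.4% with DESeq2's size factors). The trend's count was 2616 or 2186 without a 120 min replicate (23.9% or 21.1% higher). Per hour, EGR1 fell by 1.08 ± 0.15 (adjusted p = 2.9e-04) and PCF11 fell by 1.03 ± 0.06 while FOXO1, a transcription factor, fell by 0.88 ± 0.06. VPS13A rose by 0.47 ± 0.06 per hour.

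**Figure D4:**
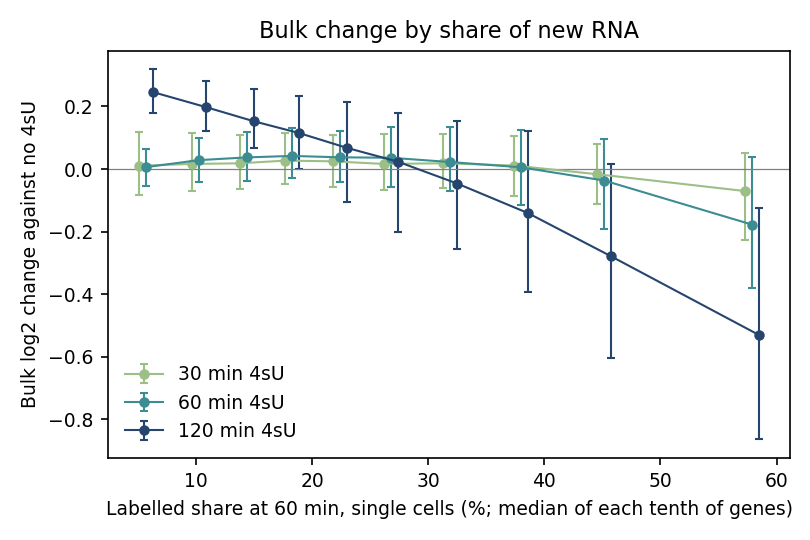
Median log2 change in bulk at 30, 60 and 120 min of 4sU against no 4sU (y axis, bars from percentile 25 to 75 of genes) for deciles of genes ordered by their labelled share at 60 min in single cells (x axis). At 120 min the medians ran from 0.25 in the decile labelled least to -0.53 in the decile labelled most.

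How far summed single cells matched bulk was asked of levels and of responses. With no 4sU, mean log2 CPM had a Pearson r of 0.854 and a Spearman rho of 0.844 across 12275 genes. The log2 changes against each assay's own controls had an r of 0.173 at 30 min (covariance 0.00645) and 0.267 at 60 min (covariance 0.0117). At 60 min 10 genes were called lower in both, against 0.385 for independent lists. They were ADAMTS1, ADM, CYR61, DDIT4, EIF4A2, ETAA1, MYC, PPP1R10, SOX4 and ZNF230. A loss of labelled RNA or reads could lower counts in both assays and was not tested for these genes. MT-ND4L alone was called higher in both, against 0.215. In the test of the difference between assays, 0 genes were called higher and 8 lower in bulk at 30 min of 15516 by edgeR, and 0 and 2 at 60 min (793 and 1003 at an unadjusted p under 0.05). DESeq2 called 0 and 14 at 30 min and 8 and 9 at 60 min. EGR1 differed at both, by -2.20 ± 0.31 (adjusted p = 0.00448) and -2.20 ± 0.30 (adjusted p = 0.00615). Short-lived regulators had a lower median in bulk at 60 min, -0.21, with 4 of 28 lower adjusted over the list alone (adjusted p = 2.2e-05, adjusted p = 0.0484 with an estimated correlation). The 30 min count was 1212 (899 higher and 313 lower) or 22 without replicate 1 or 2 of bulk 30 min and 1 or 2 without one of bulk no 4sU. It was 0 or 5 without one of single-cell 30 min and 3 or 0 without one of single-cell no 4sU. The 60 min count was 174 or 180 without one of bulk 30 min and 1 without replicate 2 of bulk 60 min or replicate 1 of bulk no 4sU. It was 0 without replicate 2 of single-cell 60 min and 0 or 5 without one of single-cell no 4sU.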

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

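The tests of the difference between assays were planned. In this part the bulk medians of genes with and without copies, and leaving out libraries, were chosen after the result was seen. The response to 4sU differed between bulk and single cells, by edgeR's interaction of assay and duration, for 8 genes at 30 min and 2 at 60 min, and with all libraries in the fit the change was lower in bulk in each. EGR1, an immediate early transcription factor, differed by -2.20 log2 at 30 min (adjusted p = 0.00448, -1.53 in bulk and 0.69 in single cells) and by -2.20 at 60 min (adjusted p = 0.00615, -1.73 in bulk and 0.47 in single cells). TRIB1, a pseudokinase, differed by -1.13 (adjusted p = 0.0166, -1.10 in bulk and 0.05 in single cells) and the exchange factor RASGEF1B by -1.33 (adjusted p = 0.0260, -0.60 in bulk and 0.75 in single cells). STEAP1B differed by -1.27 (adjusted p = 0.0363, -0.72 in bulk and 0.56 in single cells). The autophagy regulator AMBRA1 differed by -0.93 (adjusted p = 0.00608, -0.19 in bulk and 0.76 in single cells). With no 4sU, AMBRA1 held 54 of the 531 spliced counts called labelled, the most of any gene, so its single-cell counts are uncertain. The noncoding RNA AC004448.2 differed by -1.43 at 30 min (adjusted p = 0.00411, -0.14 in bulk and 1.31 in single cells) and by -1.31 at 60 min (adjusted p = 0.00786, -0.32 in bulk and 1.00 in single cells). RPL17 of the large ribosomal subunit differed by -1.26 (adjusted p = 0.0170, -0.25 in bulk and 1.03 in single cells). HNRNPA1P48, a copy of the splicing factor gene HNRNPA1, differed by -1.32 (adjusted p = 0.0170, -0.21 in bulk and 1.13 in single cells). Without replicate 1 of bulk 30 min the counts were 1212 at 30 min (899 higher and 313 lower) and 174 at 60 min (91 higher and 83 lower), so this direction did not hold there. Without replicate 2 they were 22 (22 lower) and 180 (91 higher and 89 lower). Without replicate 2 of single-cell 60 min or replicate 1 of single-cell no 4sU none was called at 60 min by edgeR (1003 at an unadjusted p under 0.05 and 17 by DESeq2 with all libraries).

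RPL17, HNRNPA1P48 and H3F3A were higher in single cells with 4sU and may share reads with near-identical copies. Such sharing could move counts between copies where a converted base changes the best match. Tested on genes called at 30 or 60 min, the odds of a pseudogene copy were 1.19 times those of other tested genes of like expression (95% interval 0.604 to 2.36), which leaves this open. A change in the cells stays open too. The 7 genes with copies called higher at 60 min in single cells (CLIC1, FABP5, H3F3A, HMGN2, LSM12, PGAM1 and RPL17) had a median of 0.50 there and of -0.01 in bulk (95% interval -0.04 to 0.04). The 18 other genes called higher in single cells, HNRNPA1P48 among them because it is annotated as protein-coding, did little more in bulk, with medians of 0.59 and 0.06 (95% interval -0.05 to 0.13). At 120 min in bulk, 9 of these 25 genes were called higher, against 3.61 for independent lists, with CLIC1, HMGN2, PGAM1 and HNRNPA1P48 among them. The intervals of the medians came from resampling genes and leave out the spread between libraries. A difference between the assays in how reads were counted was not tested.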

How the results depend on the processing

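Spliced counts alone, deep cells, the shared pair of runs, leaving out libraries in the phase and assay comparisons and every alternative for labelled counts and labelled share were chosen after the results were seen. The cause of the shifts below was not tested. Of 331 alternative counts and values, 213 stayed within the limits set for them (100 of 170 with a library left out and 113 of 161 others). By DESeq2 the calls were 31, 126, 19, 14 and 17 for single-cell 60 min, bulk 30 min, the single-cell trend and the assay difference at 30 and 60 min, against 49, 14, 3, 8 and 2 by edgeR. With no filter they were 128, 138, 132, 20, 16 and 18 for single-cell 30 and 60 min, bulk 30 min, the trend and the assay difference. Cells of at least 10000 counts gave 308, 19 and 16 calls at 15, 30 and 60 min. The shared pair of runs gave 97 and 84 at 30 and 60 min. For S against G1, G2/M against G1 and G2/M against S, thinned cells gave 908, 580 and 1899 calls and the libraries with no 4sU alone 462, 249 and 938, against 3093, 2448 and 5600. In the same order, labelled counts (468, 229 and 1341) gave 199, 124 and 790 by DESeq2 and 89, 95 and 533 without 60 min. They gave 232 and 152 in the first 2 without 30 min and 273 and 840 in S against G1 and G2/M against S without cells near a boundary. The labelled share (44, 166 and 274) gave 12, 46 and 125 by DESeq2, 25, 89 and 149 without 30 min and 3, 36 and 40 without 60 min. It gave 85 and 170 in the last 2 without cells near a boundary. With an estimated correlation, 7 of 105 list calls over the planned comparisons held. At a mean of at least 10 CPM, r of bulk and single cells was 0.752 for levels and 0.232 and 0.329 for responses at 30 and 60 min.

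With each library left out in turn, calls ranged over 194 to 830 at 15 min, 13 to 83 at 30 min, 10 to 81 at 60 min and 5571 to 7286 at 24 h in single cells. In bulk they ranged over 1 to 5129, 2 to 3223 and 2020 to 8024 at 30, 60 and 120 min. They ranged over 0 to 9 and 2186 to 6381 for the single-cell and bulk trends, and 0 to 1212 and 0 to 180 for the assay difference at 30 and 60 min. For S against G1, G2/M against G1 and G2/M against S they ranged over 2631 to 3098, 2124 to 2461 and 5202 to 5452 in all counts. With labelled counts the ranges were 229 to 424, 146 to 242 and 871 to 1272, and with labelled share 17 to 46, 57 to 148 and 125 to 259. Where a count reached 0, edgeR was the tool, with 1198, 793 and 1003 genes at an unadjusted p under 0.05 and 19, 14 and 17 by DESeq2 with all libraries for the trend and the assay difference. Of 1181 calls of named genes, 604 kept call and direction in every alternative. Of 19572 values 2260 lost the call and 7 changed sign. In S against G1 these were NR4A1 (-0.407), SESN2 (0.0201) and SLC16A1 (-0.0219) with the libraries with no 4sU alone and HIST2H2AC (0.0126) without cells near a boundary. Between G2/M and G1 they were IRF1 (0.0379) and EXOSC5 (0.0822) with the libraries with no 4sU alone and HIST1H4C (-0.0011) without 24 h.

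The replicate numbers were not taken to pair the libraries, since not every pair of groups passed an r of 0.1. Deviations from the group means of libraries with the same number correlated from -0.212 to 0.384 over 10 pairs of single-cell groups (3 over 0.1). In bulk they correlated from -0.00828 to 0.306 over 6 pairs (4 over 0.1). With the number as a block, calls at 15, 30 and 60 min and 24 h were 732, 58, 56 and 7168 in single cells. They were 12, 525 and 4841 at 30, 60 and 120 min in bulk and 4766 in the bulk trend with the block. The single-cell trend gave 0 by edgeR with the block against 3 without (1198 at an unadjusted p under 0.05 and 19 by DESeq2 without it). With the block, 66 of 70 list calls held, and it changed no other count by over 1.5 times.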

Other observations

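In this part, the tests of the 15 min and 24 h calls and the permuted phase labels and random scores for all counts were chosen after the results were seen. In bulk, transcripts with a high labelled share fell as 4sU lasted longer. The change at 120 min dropped by 0.14 log2 per 10 percentage points of labelled share. Gene and transcript length did not carry the slope, of which 118% was left with both lengths in the regression (95% interval 116 to 120.0). At the same labelled share, transcripts rich in U fell more than those rich in A, with a difference of coefficients of -2.08 log2 per unit fraction (95% interval -2.42 to -1.75), which is consistent with a loss of converted reads in mapping. A loss of 4sU-rich RNA before sequencing would give the same and was not told apart. In single cells at 60 min the median log2 change also fell with the share. It was 0.03 in the decile labelled least and -0.14 in the decile labelled most. In bulk at 60 min these medians were 0.01 and -0.18. The regression was not run for single cells, so a loss of labelled RNA or reads stays open for their falls as well. Lower synthesis under 4sU stays open, since unspliced single-cell counts of the genes lower at 60 and 120 min in bulk had a median change of -0.09 relative to all genes (95% interval -0.29 to 0.03, 107 of 368 genes had such counts). The intervals of this paragraph came from resampling genes, which are not independent replicates. They leave out the spread between libraries.

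The many calls at 15 min and 24 h in single cells came from libraries of other runs and of deeper cells than the controls. Cells under 10000 counts as the whole cause of the 24 h calls were argued against, since 80.4% were called the same way among cells of at least 10000 counts. At 15 min 43.4% of the calls were called the same way among such cells. This floor did not make depth equal. Percentile 95 of counts per kept cell was 20457.5 and 15670.8 with no 4sU against 64105 and 68641 at 24 h. Depth of the cells thus stays open as a cause. The run may explain part, and could not be excluded. Changes at 15 min against 30 min and at 24 h against 60 min, which share no library, had an r of 0.0493 across genes (95% interval -0.0123 to 0.108, from resampling genes). A change in the cells over 24 h of 4sU also stays open, since the runs at 15 min and 24 h each held a single duration. Removing genes called the same way at 15 min left 96.0% of the 24 h calls. This decides nothing, because the 632 calls at 15 min were too few against 7123 at 24 h to leave much less.

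Whether the counts of calls between phases exceed those of other groupings of the cells stays open, since phases were assigned from the counts of the same cells and a random score can also set its groups apart from permuted labels. Phase labels were permuted within libraries. The real value was the highest of 41 for all counts and for labelled counts and of 31 for the labelled share. For all counts there were 3093 calls against at most 0 in permuted labels for S against G1, 2448 calls against at most 572 for G2/M against G1 and 5600 calls against at most 1895 for G2/M against S. For labelled counts there were 468 calls against at most 264, 229 calls against at most 218 and 1341 calls against at most 49 in the same order, and for the labelled share 44 calls against at most 23, 166 calls against at most 17 and 274 calls against at most 43. Scores from random lists, run for all counts only, gave up to 4374 calls for S against G1 and 2513 for G2/M against G1, above the real counts, and up to 1947 for G2/M against S, in 5 draws. None of these draws called as many held-out genes, with at most 20 S-phase genes called either way in S against G1 (real 43) and at most 17 G2 and mitosis genes in G2/M against G1 (real 47).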
